A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

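Poly(A) RNA from the brain and the cecum of germ-free (GF) and specific-pathogen-free (SPF) mice, and from HCT116 cells, a human colorectal carcinoma line, was read by nanopore direct RNA sequencing with the SQK-RNA002 kit on Mk1C and GridION instruments, per the labels' protocols. In this assay the RNA strand itself passes through the pore, without PCR, so that 1 read stands for 1 RNA molecule. GF animals are raised without microorganisms, and SPF animals carry a microbiota without listed pathogens. The cells had been transfected with an empty pcDNA3 plasmid or with a plasmid for NSUN2, an RNA cytosine methyltransferase that writes m5C, and were collected after 48 h. Each combination of tissue and status had 3 libraries and each plasmid had 2, which made 16 libraries. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The labels do not tie a library to either of the instruments named.

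Per the submitters' processing notes, minimap2 2.17-r941 and SAMtools were used with the mm39 and hg38 builds. The tool that made the estimated counts is not given in the sources used here. Per the file headers, the authors deposited for each library the estimated count of reads per RefSeq transcript, which need not be whole. The authors also deposited the same values as TPM and as a fraction of the library. The deposited TPM differed from the estimated count over the library's total by at most 3.4e-08 of that total in any transcript, so it was not divided by transcript length. TPM and fraction therefore carried no further information and were not used here. Modification calls are not analysed here.

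Mouse transcripts were given gene symbols through RefSeq accessions of the GRCm38.p6 annotation, matched without the version suffix. Of 78553 mouse transcripts with reads, 62554 matched a gene, 39092 of them in the same version. Because that assembly is not the build the files used, no coordinates are given. Estimated counts were summed over the transcripts of a gene and rounded to whole numbers, which gave 16461 genes with reads. Transcripts that matched no gene held between 6.3% and 8.0% of a library's reads and were left out of gene totals, library sizes and gene tests. They stayed in the tests of single transcripts, where counts were rounded too. Of the 59928 human transcripts 0 matched, since no human annotation was used here. The tests planned for HCT116 genes, transcript usage and gene lists were for that reason not run, and HCT116 was compared per transcript. Mitochondrially encoded transcripts were not analysed here, because the annotation gives none of them a transcript accession.

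Counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, its default low-count filter and robust quasi-likelihood fits. A gene or transcript was called at a Benjamini-Hochberg adjusted p below 0.05. GF was compared with SPF within the cecum and within the brain, each from the tissue's own 6 libraries. The difference between the 2 effects was tested as an interaction over all 12 mouse libraries, and cecum was compared with brain within SPF mice. Transcript usage, the share of a gene's reads on each transcript, was tested with edgeR's diffSpliceDGE and Simes p-values per gene, over genes with at least 2 tested transcripts. Gene lists with 5 or more tested members were compared with all other genes by camera of limma 3.58.1 with its preset correlation of 0.01. Beside it stand camera with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance one way. Every adjusted p for genes and transcripts is from the edgeR test unless another tool is named. A range over all alternatives for the level of a gene or transcript also covers DESeq2 and limma voom. Every adjusted p is by Benjamini-Hochberg over the features or lists of its comparison. Fold changes are log2, GF minus SPF unless stated, with their standard error (SE). Levels are means of TMM-scaled CPM values (counts scaled to a common library size) ± SD over the 3 libraries of a group.

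The comparisons, tests, alternatives and 57 mouse gene lists were fixed before the data were examined, as was the rule for the genes named. Among called genes whose libraries of 1 group all lay above those of the other, with at least 20 CPM on average in the higher group, the rule took the 8 largest changes in each direction without predicted genes. It added up to 4 members of smallest p from each list that was called or had a called member, and every called RNA modification enzyme. Where under 5 genes passed, it took the 5 of smallest p. For transcript usage it took 5 genes and for the interaction 6, by smallest p. Some genes it took are not reported here. Of 1117 list members 1102 matched a gene symbol. The rule also asked for Nsun2 in mice, which is not analysed here because it had no values in the gene table.

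Where all libraries of a group had 0 reads, a fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads in a group, the ratio of summed counts is given with its exact 95% interval. Intervals and floors cover counting error only. The total per library ran from 273136 to 1314249 reads in mice and from 95089 to 202258 in HCT116. Tests of genes, transcripts and usage were run on simulated data in which 200 features were changed by known folds, and list tests on data in which 1 list was changed, which was recovered. The simulated counts were drawn independently for each feature at the fitted trend of the dispersion. They held no outlying library and no correlation between genes, so recovery in the real data may be lower, also for lists. For 2-fold and 4-fold changes, the shares recovered were 51.0% and 98.0% for cecum genes (5171 genes in the run), 68.7% and 99.0% for brain genes (8653 genes), and 15.3% and 42.9% for the interaction (9393 genes). They were 34.4% and 93.8% for cecum transcripts, 31.2% and 78.4% for brain transcripts, 4.60% and 54.7% for cecum transcript usage, and 3.33% and 32.2% for brain transcript usage. For the comparison of cecum with brain they were 50% and 99.0%. In HCT116 transcripts they were 1.09% and 29.8%.

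The alternatives were DESeq2 size factors, looser and stricter filters on low counts, DESeq2 1.42.0 and limma voom as other tests, the replicate number as a block, all 12 mouse libraries in 1 fit, and each library left out in turn. Added after the data were seen were a fit without scaling factors, covariates for the level of smooth muscle genes in cecum and of cerebellar genes in brain, voom on transcripts, further settings for HCT116 and thinning of the cecum libraries to 329393 reads in 10 draws. Tables were made and plotted with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.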

Results

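The series asked how the gut microbiota bears on RNA in the gut and in the brain. Native poly(A) RNA of the brain and of the cecum, the pouch at the start of the large intestine where bacteria are dense, was read from GF and SPF mice, with 3 libraries in each of the 4 groups. A separate pair of groups, with 2 libraries each, compared HCT116 cells given an empty plasmid with cells given NSUN2. The GF brain libraries 1, 2 and 3 held 1314249, 1040761 and 793768 reads, and the SPF brain libraries held 273136, 763713 and 1089946. The GF cecum libraries held 601084, 677589 and 1086552 reads, and the SPF cecum libraries held 416495, 352528 and 467918. The pcDNA3 libraries held 121622 and 202258 reads and the NSUN2 libraries 182494 and 95089. The spread between libraries of a group beyond counting error was 17.3% of a gene's level in cecum, 12.1% in brain, and 30.5% of a transcript's level in HCT116. No pair of libraries in a group agreed within sampling noise (lowest chi-square per degree of freedom 1.49), so each was counted once. SPF cecum library 1 stood apart from libraries 2 and 3 of its group, with 8.54 and 8.67 against 1.78 between those 2.

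In the cecum, interferon-stimulated genes, the antiviral effectors induced by interferon signalling, were far lower in GF than in SPF mice. Isg15, a ubiquitin-like modifier, averaged 384 ± 54.3 CPM in SPF and 5.06 ± 4.45 CPM in GF cecum (SD, n = 3 each), a log2 fold change of -6.00 ± 0.35 (SE; edgeR adjusted p = 3.27e-06). Oasl2, of the oligoadenylate synthetase family, fell from 467 ± 80.5 to 10.8 ± 5.70 CPM (log2 -5.42, edgeR adjusted p = 7.06e-07), and Rtp4 fell from 116 ± 29.1 to 2.61 ± 1.36 CPM. The nucleic acid sensor Zbp1 had a log2 fold change of -4.95 ± 0.29. Of the 23 list members tested 22 fell and 0 rose, with a median log2 fold change of -4.28, and 23 passed when adjusted over the list alone. Oas2 and Ifi44 had 0 reads in GF cecum against 62 and 41 in SPF, so they were at least 37.3-fold and 24.7-fold lower, and the list's median was -4.28 also with these genes at their bounds. Usp18, which trims Isg15 from proteins, had 2 GF reads against 62 SPF reads, a ratio of 56.0 with a 95% interval from 14.9 to 472.5. Apol9a (log2 -5.46 ± 0.36) and Apol9b (2 GF against 74 SPF reads) are near-identical neighbours, and how the reads divided between them is uncertain, as it is among Oas and Ifit genes. The list was called by limma's camera (Benjamini-Hochberg adjusted p = 3.24e-109), and also with an estimated correlation (adjusted p = 0.00733) and by fry (adjusted p = 0.000731). Summed over 51 marker genes of leukocytes, the level was 154.5, 155.8 and 244.9 CPM in the GF and 377.9, 552.5 and 185.5 CPM in the SPF cecum libraries, while the listed interferon-stimulated genes summed to 509.8, 520.9 and 609.7 CPM in GF and 4819, 3722 and 5107 CPM in SPF. The leukocyte sums rest on 81 to 249 reads per library.

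**Figure D1:**
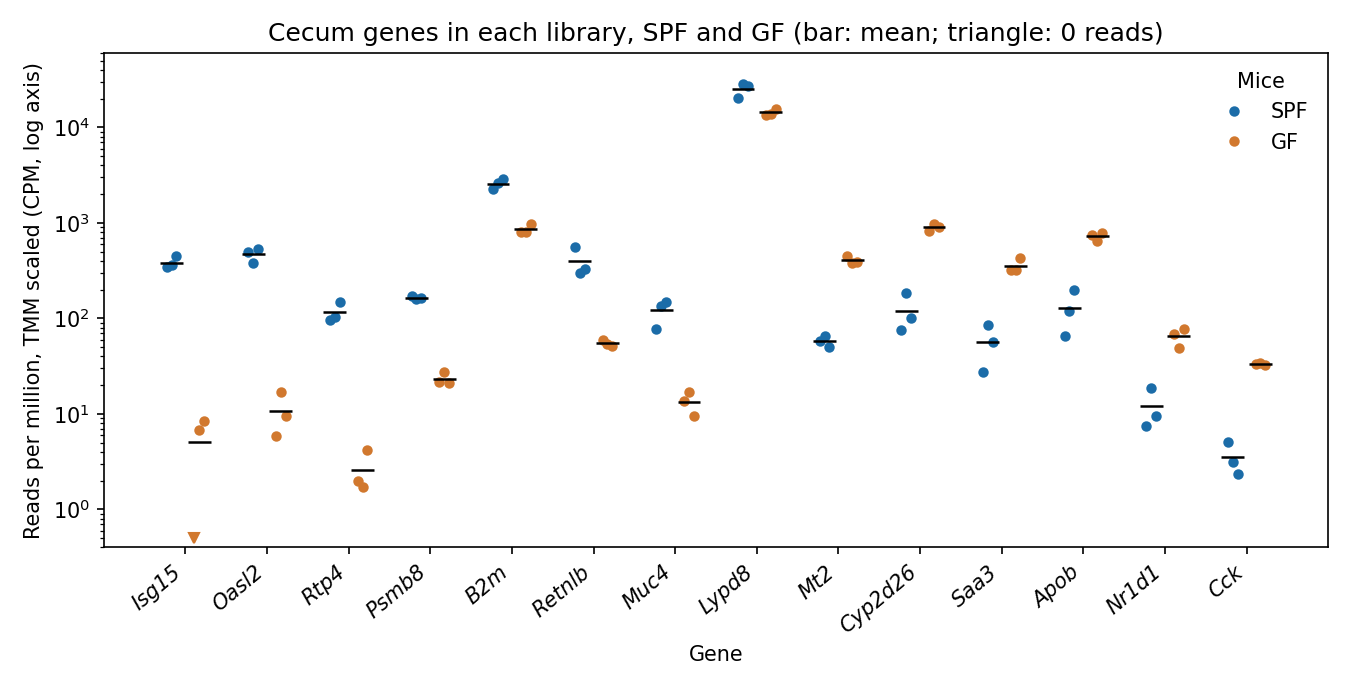
Normalised counts in CPM (log axis) of 14 genes in each of the 3 GF and 3 SPF cecum libraries, with a point per library, a bar at the group mean and a triangle for 0 reads. Isg15, at 384 CPM on average in SPF, had 0 reads in 1 GF library, and Mt2 rose from 57.9 to 406 CPM.

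Genes of MHC class I antigen presentation also fell in GF cecum. B2m, the light chain of class I molecules, dropped from 2581 ± 309 to 860 ± 97.3 CPM (log2 -1.58 ± 0.14, edgeR adjusted p = 2.66e-05), and the immunoproteasome subunit Psmb8 from 165 ± 5.26 to 23.2 ± 3.49 CPM (log2 -2.83 ± 0.21). Psmb9 changed by -2.63 and the peptide transporter Tap1 by -3.24 on the log2 scale. Of 11 members tested 8 fell, 0 rose and 9 passed when adjusted over the list alone, with a median log2 fold change of -1.27. Camera called the list (adjusted p = 1.26e-18 by limma with Benjamini-Hochberg, adjusted p = 0.0131 with an estimated correlation). All 3 interferon-gamma induced GTPases tested fell, with log2 fold changes of -3.46 for Ifi47, -2.56 for Irgm2 and -1.72 for Irgm1, and all 3 passed when adjusted over the list alone. Ly6a, an interferon-responsive surface protein and the 1 endothelial marker tested (1 adjusted over the list alone), fell from 750 ± 374 to 24.6 ± 6.60 CPM (edgeR adjusted p = 0.00250). Of MHC class II genes 4 were tested and 0 called by edgeR, with 0 at an unadjusted p below 0.05 and 0 by DESeq2 or voom.

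Among mucus and defence genes of the cecal epithelium, calls went in both directions. Retnlb, a goblet cell protein secreted toward bacteria, fell from 395 ± 139 CPM in SPF to 54.8 ± 3.78 CPM in GF (log2 -2.86 ± 0.24, edgeR adjusted p = 3.11e-05), and the membrane mucin Muc4 fell from 121 ± 37.9 to 13.4 ± 3.82 CPM (log2 -3.21 ± 0.33). Lypd8, which keeps flagellated bacteria off the colonic surface, was abundant and fell from 25415 ± 4315 to 14304 ± 1011 CPM (log2 -0.83 ± 0.14, edgeR adjusted p = 0.00348). The serum amyloid gene Saa3 rose instead, from 56.5 ± 28.7 to 357 ± 59.5 CPM (log2 2.70 ± 0.29, edgeR adjusted p = 0.000299). The antibacterial lectin Reg3g averaged 182 ± 115 CPM in SPF and 4.05 ± 5.61 CPM in GF (log2 -5.09 ± 0.90, edgeR adjusted p = 0.0282), but it did not pass without GF library 1, 2 or 3 (edgeR adjusted p = 0.102, 0.124 and 0.0556) or without SPF library 1 or 3 (0.0898 and 0.0810), and over all alternatives its adjusted p ran from 0.000252 to 0.127. Of 16 antimicrobial and barrier genes tested 2 rose, 4 fell and 9 passed when adjusted over the list alone, with no call of the list (camera adjusted p = 0.0804, limma). The list was called as lower in GF without SPF library 1 (adjusted p = 6.44e-09), without SPF library 2 (0.0139) and with the replicate number as a block (0.00240), while other alternatives reached up to 0.405. Of 15 goblet cell and mucus genes tested 3 fell, 0 rose and 5 passed when adjusted over the list alone, with a median log2 fold change of -0.76 (camera adjusted p = 0.0377, limma), a call lost with an estimated correlation (adjusted p = 0.328) and without GF library 1, 2 or 3 (adjusted p = 0.0501, 0.0790 and 0.0948). Of the 3 falling members Muc4 held in every fit. Spink4 was lost without GF library 1 or 3 or SPF library 3 (edgeR adjusted p up to 0.0861). Galnt12 was lost without GF library 1 or 2 (edgeR adjusted p up to 0.0862). Over all alternatives by edgeR, DESeq2 or limma the lowest adjusted p was 0.000130 for Spink4 and 7.99e-06 for Galnt12. Proliferation genes had a median log2 fold change of -0.61 over 13 tested members, of which 0 were called by edgeR, 5 had an unadjusted p below 0.05 and 0 passed when adjusted over the list alone (0 called by DESeq2 and 0 by voom). Mki67 (-0.81) and Top2a (-0.88) did not pass (edgeR adjusted p = 0.0987 and 0.101). That list was called by camera (adjusted p = 0.0264, limma), and the call was lost with an estimated correlation (adjusted p = 0.777), without GF library 3 (0.136) and without SPF library 1 (0.273). SPF cecum library 1 had the highest level of both lists, 0.86 above the mean over the libraries for goblet and 0.60 for proliferation genes on the log2 scale. Over 9 alternatives the adjusted p ran from 0.000863 to 0.328 for the goblet and from 0.000368 to 0.777 for the proliferation list.

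Several metabolic and hormone genes rose in GF cecum. Mt2, a metal-binding metallothionein, rose from 57.9 ± 8.12 to 406 ± 38.7 CPM (log2 2.82 ± 0.17, edgeR adjusted p = 3.14e-06). Apob, the structural protein of lipoproteins, rose from 127 ± 66.1 to 719 ± 67.8 CPM (log2 2.49 ± 0.32), and Slc51a, a subunit of the basolateral bile acid exporter, from 263 ± 49.4 to 634 ± 51.3 CPM (log2 1.26 ± 0.16, edgeR adjusted p = 0.000431). The satiety hormone Cck rose from 3.51 ± 1.36 to 33.2 ± 0.83 CPM (log2 3.15 ± 0.46), and the endothelin genes Edn1 and Edn3 had log2 fold changes of 2.75 and 3.11. The gluconeogenic enzyme gene Pck1 fell, from 189 ± 55.6 to 67.2 ± 15.8 CPM (log2 -1.46 ± 0.25, edgeR adjusted p = 0.00440). It is 1 of 3 adipocyte markers tested, of which 2 passed when adjusted over the list alone, and another of them, Lpl, was at -1.15 (edgeR adjusted p = 0.174). Among xenobiotic metabolism genes 4 of 27 rose and 0 fell, with 9 passing when adjusted over the list alone, led by Cyp2d26 (120 ± 57.9 to 897 ± 78.8 CPM) and the epoxide hydrolase Ephx2 (log2 1.51). Reads of Cyp2d26 can be shared with close copies of the Cyp2d family. Ankrd37 (2 SPF against 75 GF reads) and the organic cation transporter gene Slc22a4 (2 against 58) were higher in GF by ratios of 20.8 (95% interval 5.55 to 175) and 16.1 (4.25 to 136). The clock repressor Nr1d1 rose from 12 ± 6.06 to 65.1 ± 14.3 CPM (log2 2.50 ± 0.36, edgeR adjusted p = 0.00125). Its clock output partner Tef was at 7.42 ± 7.96 and 45.0 ± 11.7 CPM (log2 2.52 ± 0.51, edgeR adjusted p = 0.0114), a call lost without GF library 3 (edgeR adjusted p = 0.0736) and by voom (limma adjusted p = 0.0536), with adjusted p from 3.67e-07 to 0.0736 over all alternatives.

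None of these metabolic lists was called in 1 direction as a whole with all 6 libraries. Fry's mixed test, which asks for change in either direction without comparison to other genes, did pass for them. Its adjusted p (limma) ran from 2.68e-05 for lipid uptake and PPAR targets to 0.00138 for butyrate oxidation and ketogenesis. Camera's adjusted p (limma) was 0.308 for xenobiotic metabolism, 0.950 for lipid uptake and PPAR targets, 0.495 for colonocyte transport, 0.0804 both for bile acid transport and for butyrate oxidation and ketogenesis, 0.293 for the clock and 0.969 for enteroendocrine genes. Without SPF library 1, bile acid transport (adjusted p = 0.00283, up in GF) and butyrate oxidation and ketogenesis (0.0197, down) were called by camera. Over 9 alternatives the highest adjusted p of these 2 lists was 0.422 and 0.582, with an estimated correlation. Lipid uptake and PPAR target genes went both ways, 3 rising and 4 falling of 17, with 8 passing when adjusted over the list alone. Absorptive transport genes rose in 3 and fell in 1 of 17 cases (6 adjusted over the list alone), bile acid genes rose in 1 of 7 (3 adjusted over the list alone) and butyrate and ketogenesis genes fell in 2 of 14 (3 adjusted over the list alone). Of the colonocyte transport calls, Slc5a8, Slc9a2 and Scnn1a were each lost without GF library 1, 2 or 3. Over all alternatives their adjusted p (edgeR, DESeq2 or limma) reached 0.0699, 0.134 and 0.208 and went down to 0.000118, 6.04e-06 and 0.0110. The xenobiotic genes Cyp2c65 and Cyp3a13 were also lost without GF library 1, 2 or 3, while Cyp2d26 and Ephx2 held throughout. Over all alternatives the adjusted p of Cyp2c65 and Cyp3a13 (edgeR, DESeq2 or limma) ran from 6.48e-05 to 0.128 and from 6.28e-06 to 0.129. Clock genes rose in 2 of 7 cases. Enteroendocrine genes rose in 1 and fell in 1 of 7. In each of these 2 lists 5 passed when adjusted over the list alone. Before TMM scaling, the clock gene Arntl was at 35.53, 29.9 and 42.29 CPM in GF and 51.77, 75.9 and 93.9 CPM in SPF cecum. Npas2 was at 15.99, 17.31 and 23.6 CPM in GF and 28.47, 54.65 and 43.52 CPM in SPF. Both were lower in every GF library, opposite to Nr1d1 and Tef, while Nr1d2 was higher and Cry1 overlapped. Camera asks for change in 1 direction, so its 0.293 cannot decide on opposite changes among clock genes. Smooth muscle genes had 0 calls among 16 by edgeR (0 at an unadjusted p below 0.05, 0 by DESeq2 or voom), with levels per library from -0.73 in GF library 1 to 0.59 in GF library 3 relative to the mean. The list was called as higher in GF without GF library 1 (camera adjusted p = 0.0207, limma), the lowest of 9 alternatives, the highest of which was above 0.99. RNA modification enzymes, writers, erasers and readers of m6A, m5C, pseudouridine and other marks, showed 1 call among 19 tested in cecum and 0 among 40 tested in brain by edgeR, with 1 and 0 at an unadjusted p below 0.05 and 1 and 0 when adjusted over the list alone. The called gene was the m6A reader Igf2bp2, with 49.2 ± 12.9 CPM in SPF and 17.6 ± 7.52 CPM in GF cecum (log2 -1.58 ± 0.37, edgeR adjusted p = 0.0247), a call lost without GF library 2 or 3 (edgeR adjusted p = 0.104 and 0.130) and without SPF library 3 (0.125), with adjusted p from 0.00123 to 0.130 over all alternatives.

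In all, 339 of 5430 genes tested differed between GF and SPF cecum by edgeR at a Benjamini-Hochberg adjusted p below 0.05, of which 172 were higher and 167 lower in GF. Without scaling factors 338 genes were called, but 119 higher and 219 lower. The median log2 fold change of all genes was -0.12 without scaling and -0.01 with it. Leaving out GF library 1, 2 or 3 gave 155, 148 and 171 calls, and leaving out SPF library 1 gave 607.

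In the brain, 0 of 8929 genes passed by edgeR, and 307 had an unadjusted p below 0.05. DESeq2 and limma voom also called 0. The smallest adjusted p was that of Mup2, a major urinary protein gene, with 39 SPF reads and 2 GF reads, a ratio of 29.0 with a 95% interval from 7.52 to 248 (edgeR adjusted p = 0.139). The chromatin organizer Ctcf averaged 17.2 ± 6.95 CPM in SPF and 50.4 ± 8.05 CPM in GF (log2 1.65 ± 0.30, edgeR adjusted p = 0.232), and neither it nor Ncoa1, Alb or Mapk10, the next by p, passed. When every gene with 1 read was tested, Mup2, Ctcf, Ncoa1 and Alb passed (edgeR adjusted p at most 0.00736, that of Alb). Under other alternatives the adjusted p of Mup2 reached 0.866, and that of the other 3 reached 1.00. Without SPF library 1 there was 1 call, the pituitary hormone gene Prl (edgeR adjusted p = 0.0308), named because it was the call and so after its value was seen. The interferon-stimulated and MHC class I lists, lower in GF cecum, had median log2 fold changes of 0.12 over 6 and 0.01 over 7 tested genes in brain, with 0 calls in each by edgeR, 0 and 1 at an unadjusted p below 0.05 and 0 and 1 when adjusted over the list alone.

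Of 33 lists tested in brain 2 were called by camera (limma, Benjamini-Hochberg), and neither call held under other list tests. Markers of meninges and pericytes had a median log2 fold change of -0.19 over 9 genes (adjusted p = 0.0131), with Aldh1a2 at -1.02 and Dcn at -0.87, and erythrocyte markers -0.17 over 6 genes (adjusted p = 0.0498), with the globins Hbb-bt at -0.39 and Hbb-bs at -0.22. By edgeR 0 members of either passed, over all genes or adjusted over the list alone, and 2 and 1 had an unadjusted p below 0.05. The adjusted p was 0.699 and 0.905 with an estimated correlation and 0.919 for each by fry. The meninges call was lost without SPF library 2 (0.171), and the erythrocyte call without GF library 2 (0.431), SPF library 2 (0.336) or SPF library 3 (0.115). Cerebellar neuron markers differed between single libraries rather than groups, at 0.81, 0.96 and -0.94 in GF and 1.02, -1.08 and -0.63 in SPF relative to the mean on the log2 scale (list median 0.63 over 13 genes, camera adjusted p = 0.315). The list was called as higher in GF without GF library 3 (adjusted p = 1.85e-06) and, at a lower adjusted p, without SPF library 1, against 0.919 by fry.

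**Figure D2:**
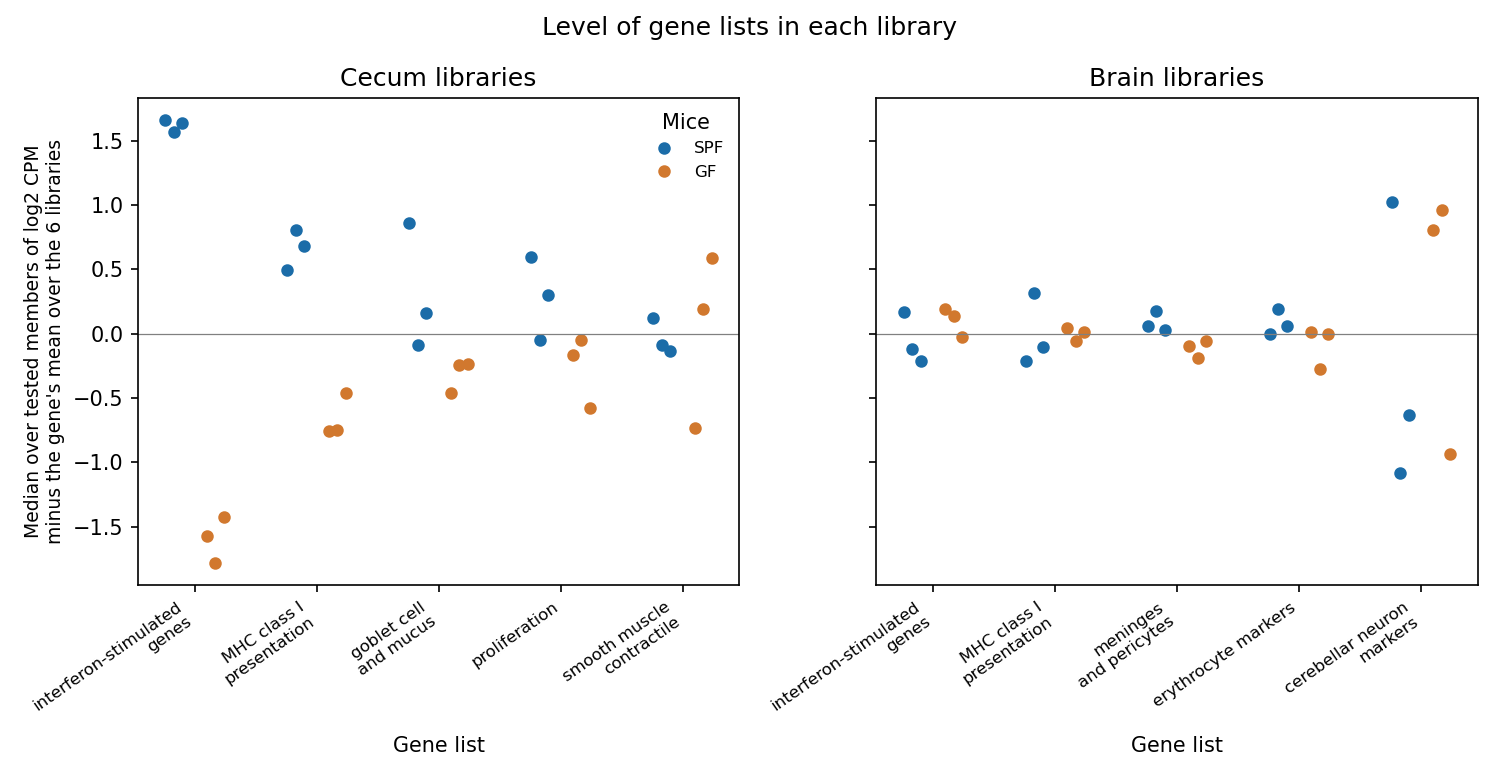
Level of 10 gene lists per library, as the median over list members of log2 CPM minus the gene's mean over the 6 libraries of the tissue, with a point per GF or SPF library. The GF and SPF cecum libraries part on interferon-stimulated genes, from -1.78 to -1.43 against 1.57 to 1.66, while cerebellar markers in brain run from -1.08 to 1.02 across both groups.

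Whether the GF effect differed between the tissues was tested directly. By the interaction term of edgeR 63 of 9617 genes passed, 26 with a more positive and 37 with a more negative effect in cecum. Selenom, a selenoprotein of the endoplasmic reticulum, changed by -2.33 in cecum and 0.34 in brain, a difference of -2.65 ± 0.23 on the log2 scale (edgeR adjusted p = 1.00e-06). B2m changed by -1.58 and 0.13, a difference of -1.69 ± 0.20 (edgeR adjusted p = 5.91e-05), and Ifit2 differed by -5.54 ± 0.73 with too few brain reads for a test there alone. Mt2, the retinaldehyde dehydrogenase gene Aldh1a1 and the transferrin receptor gene Tfrc differed by 3.13, 2.55 and 2.48, with changes of 2.82, 2.37 and 2.57 in cecum against -0.29, -0.14 and 0.12 in brain. Of the 63 genes 57 were tested within cecum, and all 57 were called there. Only 41 of the 63 were tested in both tissues, and the others had too few reads in 1 of them. On the interferon-stimulated list were 13, although only 6 members of that list were tested in brain, and 3 were on the MHC class I list. The count was 36, 35 and 36 without GF brain library 2, SPF brain library 2 or SPF brain library 3, 31 without GF cecum library 2, and 120 without SPF cecum library 1.

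**Figure D3:**
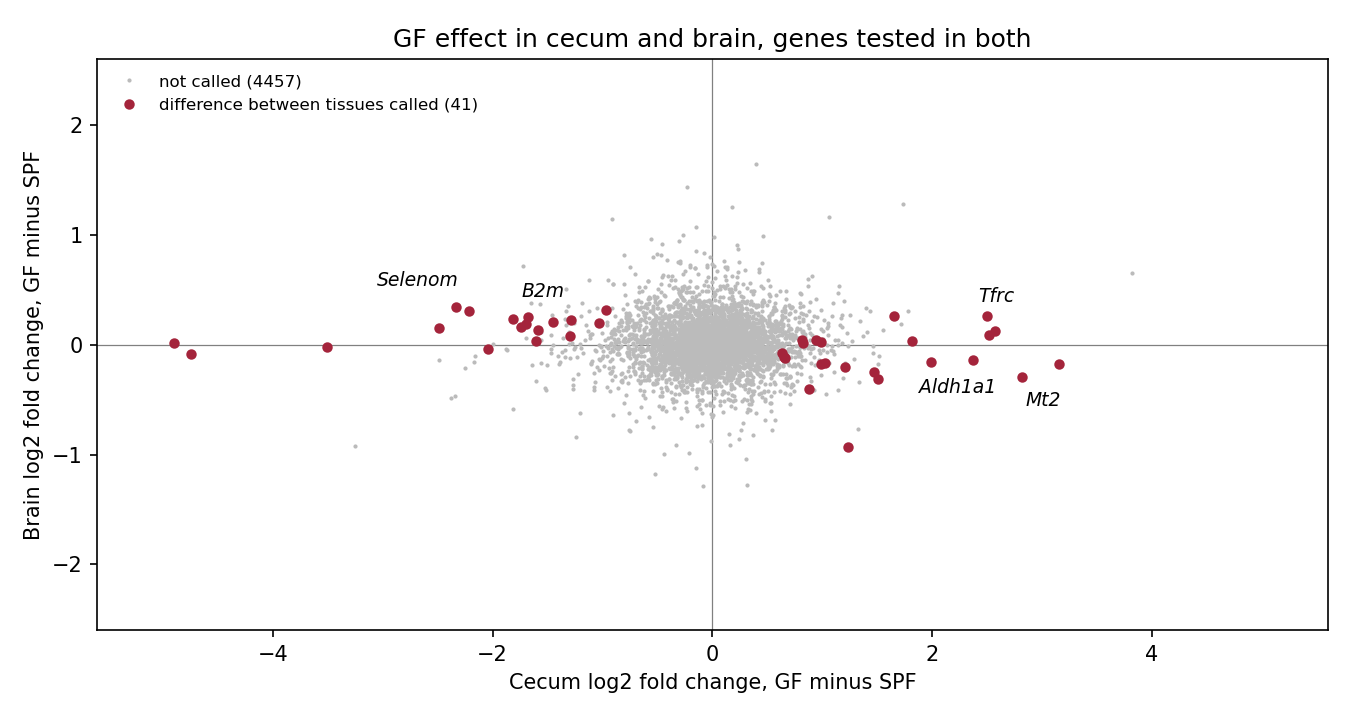
Log2 fold change, GF minus SPF, in cecum (horizontal axis) against brain (vertical axis) for the 4498 genes tested in both tissues, a point per gene, with the 41 genes called for a difference between the tissues in red. The called genes spread along the cecum axis, with a median absolute log2 fold change of 1.60 in cecum and 0.16 in brain.

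Within SPF mice, cecum and brain differed in 5062 of 7008 genes tested by edgeR, 2324 higher and 2738 lower in cecum. Genes of the colonic epithelium led one side. Lypd8 (28731 reads), the guanylate cyclase activator Guca2a (6958), the goblet cell products Zg16 (4423) and Tff3 (2571), Phgr1 (3031) and Cyp2c55 (12529) had 0 brain reads and were at least 22087, 5349, 3400, 1976, 2330 and 9632 times higher in cecum. Carbonic anhydrase gene Car1 had 41141 cecum reads against 1 in brain (ratio 94882, 95% interval 17028 to 3747730). Neuronal and glial genes led the other side. The calcium sensor Hpca (1829 brain reads), the synaptic vesicle protein gene Rab3a (1515), Ddn (1269), Nptxr (1186) and the myelin gene Cldn11 (1160) had 0 cecum reads and were at least 264, 219, 183, 171 and 168 times lower in cecum. Ptgds, the prostaglandin D synthase of the meninges and choroid plexus, had 7994 brain reads against 1 in cecum (ratio 3466, interval 622 to 136925).

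The same comparisons were made per transcript. Of 6314 transcripts tested in cecum 302 were called by edgeR, 127 higher and 175 lower in GF, and in brain 0 of 13586 were called (526 at an unadjusted p below 0.05, 0 by limma voom). The cecum count was 147, 76 and 84 without GF library 1, 2 or 3, and 129 and 84 without SPF library 2 or 3. The share of a gene's reads per transcript changed in 3 of 1127 cecum genes by edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment. In Ubl3, a membrane-anchored ubiquitin-like protein gene, the predicted transcript XM_006504832.4 fell from 13.9% ± 2.97 of the gene's reads in SPF to 2.11% ± 0.65 in GF (SD, n = 3 each; edgeR adjusted p = 0.00956), while NM_011908.2 was at 63.5% ± 7.45 and 94.1% ± 1.34. Ubl3 had 65 to 199 reads per library, so the GF shares of XM_006504832.4, from 1.52% to 2.80%, rest on very few reads. In the solute carrier gene Slc35f5, NM_028787.5 rose from 8.61% ± 4.98 to 53.9% ± 5.38 and XM_006529912.5 went from 49.0% ± 5.04 to 20.7% ± 3.96 (edgeR adjusted p = 0.0324), on 35 to 192 reads per library. In the tight junction gene Cldn7, NM_001193619.1 rose from 2.53% ± 0.99 to 6.89% ± 0.77 (edgeR adjusted p = 0.0376). Hspa8 and Tpm1 came next and did not pass (edgeR adjusted p = 0.158 for each). With 10 reads asked of every library of a group 4 genes were called, Slc35f5, Cldn7 and Tpm1 at 0.0371 each and Prkcd at 0.0387 (edgeR adjusted p), and Ubl3 was not tested. Over all alternatives Tpm1 ran from that value to 1.00. In brain 0 of 2668 genes passed the usage test (edgeR), 42 had an unadjusted p below 0.05, and the first by p, Hnrnpa1, had 25.9% ± 5.62 in SPF and 11.1% ± 1.83 in GF of NM_010447.6 (edgeR adjusted p = 1.00).

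These 3 usage calls were lost in nearly every fit without 1 library. Leaving out GF library 1, 2 or 3 gave 0 calls, with adjusted p of 0.145, 0.614 and 0.601 for Ubl3, 0.145, 0.455 and 0.601 for Slc35f5, and 0.172, 0.453 and 0.601 for Cldn7 (edgeR). Without SPF library 1 Slc35f5 was called (0.0316) and Ubl3 (0.564) and Cldn7 (0.123) were not. Without SPF library 2 all 3 were at 0.156, and without SPF library 3 they were at 0.462, 0.194 and 0.461 (edgeR).

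In HCT116, 0 of 2095 transcripts differed by edgeR between the libraries labelled NSUN2 and those labelled pcDNA3, and 50 had an unadjusted p below 0.05. DESeq2 and limma voom also called 0. NSUN2's own level was not checked here, since human transcripts were not given gene names. Transcript NM_001127695.3 averaged 61.8 ± 7.53 CPM with pcDNA3 and 193 ± 18.4 CPM with NSUN2 (SD, n = 2 each; log2 1.63 ± 0.41). NM_001369563.1 was at 295 ± 21.8 and 52.0 ± 9.81 CPM (log2 -2.53 ± 0.40), and NM_182471.4 at 259 ± 2.73 and 63.3 ± 6.13 CPM (log2 -1.99 ± 0.38), and none of these passed (edgeR adjusted p = 0.998 for each). Parting the same 4 libraries by replicate number instead of plasmid put 416 transcripts at an unadjusted p below 0.05. With 1 library left out, the lone library of its group being assumed to vary like the others, the count was 8 without pcDNA3 library 1, 3 without pcDNA3 library 2, 0 without NSUN2 library 1 and 12 without NSUN2 library 2, and NM_001369563.1 then passed without pcDNA3 library 1 (edgeR adjusted p = 0.0497) and without NSUN2 library 2 (0.0485). It also passed when every transcript with 1 read was tested (0.0415, the lowest of a range up to 1.00 over its alternatives). So did NM_001002847.4, with 2 pcDNA3 and 30 NSUN2 reads (edgeR adjusted p = 0.998 in the main test, 0.0493 with the 1-read filter and up to 1.00 under other alternatives).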

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

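The tests on leukocyte markers and on name stems of genes in this part were chosen only after the results were seen. The test on name stems replaced one that rested on 2 genes, Bst2 and Zbp1, with a median log2 fold change of -4.85.

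The GF effect differed between cecum and brain in 63 of 9617 genes by edgeR's interaction term, a difference between tissues under the same contrast. For the 6 genes of smallest p, the log2 effect in cecum minus that in brain was -2.65 for Selenom, -1.69 for B2m, 3.13 for Mt2, 2.55 for Aldh1a1, -5.54 for Ifit2 and 2.48 for Tfrc. All 6 passed under each of 18 alternatives, the highest adjusted p being 0.00262 for Tfrc without SPF brain library 2 (edgeR, Benjamini-Hochberg). When the GF and SPF labels were redrawn within each tissue, 8 of 100 splits, the real one included, gave 63 or more calls. The highest other count was 97. All 8 of those splits were among the 15 that kept the GF and SPF cecum libraries apart, with their labels real or swapped. Since such splits gave many calls whatever the brain labels, this share cannot decide on chance, which is not excluded. These 15 splits gave 52 to 97 calls, whereas the other 85, which mixed the cecum libraries, gave 0 or 1. The counts thus followed the parting of the cecum libraries, and the real labels in brain did not stand out. The count was 36, 35 and 36 without GF brain library 2, SPF brain library 2 or SPF brain library 3, 31 without GF cecum library 2 and 120 without SPF cecum library 1.

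Interferon-stimulated genes were lower in GF cecum, with a median log2 fold change of -4.28 over 23 tested genes. Depth is argued against as the cause, since the median stayed between -4.38 and -3.75 in 10 draws with every cecum library thinned to 329393 reads. Fewer leukocytes that carry these transcripts in GF cecum are argued against as the whole cause. Summed leukocyte markers differed by no more than -1.84 in any pair of a GF and an SPF library, with a mean of -0.91. The cut for this test was set after the results were seen, and the lowest pair came close to it. A sum of markers cannot bear on a single leukocyte type, or on leukocytes as a source of signals to other cells. The marker sums rest on only 81 to 249 reads per library, and 0 T and NK cell or B cell markers had enough reads to be tested singly. Sums over all genes that share a name stem were lower in all 9 pairs for 15 of 16 stems, with a median of -1.81 and pair values from -2.09 to -1.395. This cannot decide on shared reads for the whole list. Stems such as Usp (50 genes) and Trim (52) are names rather than families of copies, and Bst and Zbp hold 1 gene each. For Oas and Ifit genes the sums changed by -3.03 and -2.42 and were lower in all 9 pairs, which argues against reads merely moved among those genes. Copies under other names were not covered. As a hypothesis, microbiota status, which the design names, may account for the pattern, and other differences between the GF and SPF colonies in source, housing or health, which the labels do not give, remain open and untested.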

How the results depend on the processing

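Chosen after the data were seen were the fits without scaling factors, with a smooth muscle or cerebellar covariate, voom on transcripts, and DESeq2, its size factors and the 1-read filter for HCT116. Among called genes, counts within 1.5 times the reported one held for cecum under DESeq2 size factors (337), the 10-read filter (348), DESeq2 (237), voom (302), 1 fit of 12 libraries (437), no scaling (338) and the smooth muscle covariate (275), and for cecum against brain under all alternatives, from 4621 to 7441. Testing every gene with 1 read gave 663 calls in cecum, 10 in brain, 106 for the interaction and 10 transcripts in HCT116, where more features were tested. The cerebellar covariate gave 1 brain call, Mup2 (edgeR adjusted p = 0.0213), and voom 190 cecum transcripts. Leaving out 1 library gave 148 to 607 genes in cecum (148 without GF library 2, 607 without SPF library 1), 0 to 1 in brain (1 without SPF library 1), 31 to 120 for the interaction, 4829 to 5628 for cecum against brain, 76 to 383 transcripts in cecum, 0 in brain and 0 to 12 in HCT116. It gave 0 to 2 genes of changed usage in cecum, 2 to 8 lists in cecum (2 without GF library 3, 8 without SPF library 1) and 2 to 6 in brain (5, 4 and 6 without GF library 1, GF library 3 or SPF library 1). With an estimated correlation or by fry 2 lists were called in cecum, both of them the interferon-stimulated and MHC class I lists, and 0 in brain. Same-numbered libraries deviated together by correlations of -0.073, 0.014 and -0.004 in cecum and 0.022, -0.163 and 0.144 in brain, so the numbers do not pair them there. In HCT116 the correlation was 0.306 between same-numbered libraries. With 2 libraries per group, that between other libraries (-0.306) is its mirror and no further result. With the number as a block, 0 HCT116 transcripts were called and 83 had an unadjusted p below 0.05. With the number as a block, cecum gave 188 genes, 131 transcripts, 0 genes of changed usage and 5 lists, brain gave 0 genes and 1 list, and the interaction gave 81 genes. Over 56 cecum genes taken by the naming rule, 638 of 725 fold changes kept direction and side of the threshold, 85 fell short of it, 2 newly passed it (Muc13) and 0 reversed, and 37 genes kept both throughout. In brain 158 of 162 kept both and 4 newly passed with the 1-read filter, and all 108 for the interaction and 192 for cecum against brain kept both. Where a cause is not stated, the cause was not tested. In simulated data 15.3% of 2-fold interactions and 1.09% of 2-fold HCT116 transcript changes were recovered. HCT116 gene, usage and list alternatives were not run.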

Other observations

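The test on the hour of dissection in this part was chosen only after the result was seen.

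Housekeeping and stress lists of the cecum were not called by camera with all 6 libraries. Of those given here, nuclear oxidative phosphorylation passed fry's mixed test (adjusted p = 0.00228, limma). Nuclear genes of oxidative phosphorylation had 1 call among 21 and a median log2 fold change of 0.18 (camera adjusted p = 0.239, limma), and unfolded protein response genes had 1 call among 14 and a median of -0.07 (camera adjusted p = 0.880, limma). Of these calls Cox6c was lost in 4 of 6 fits without 1 library and Dnajb9 in 3 of 6 (edgeR adjusted p up to 0.173 and 0.138). Over all alternatives by edgeR, DESeq2 or limma their lowest adjusted p was 0.00109 and 0.000124, and DESeq2 called 0 in either list. Cytosolic ribosomal protein genes, 42 tested, had 0 calls (3 at an unadjusted p below 0.05, 0 by DESeq2 or voom) and a median of 0.13 (camera adjusted p = 0.191, limma), a value of 0.01 without scaling factors. Without SPF library 1, which stands apart from its group, the ribosomal (adjusted p = 1.75e-07) and oxidative phosphorylation lists (0.0436) were called by camera as higher in GF. Their highest adjusted p over 9 alternatives was 0.957 and 0.777. Cholesterol synthesis genes, 19 tested, also had 0 calls (3 at an unadjusted p below 0.05, 0 by DESeq2 or voom), with a median of 0.08 that turned to -0.03 without scaling factors. Fibroblast and matrix genes had 0 calls among 11 (1 at an unadjusted p below 0.05, 0 by DESeq2 or voom). Each of these calls is by edgeR, and each count was the same when adjusted over the list alone.

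Some genes of colonocyte fuel use and hormone output were called in GF cecum but lost the call when single libraries were left out. Slc5a8, which takes up butyrate, fell from 120 ± 32.7 to 52.2 ± 2.55 CPM (log2 -1.19 ± 0.24, n = 3 each, edgeR adjusted p = 0.0113), and the values were 0.0517, 0.0699 and 0.0556 without GF library 1, 2 or 3 and 0.0653 without SPF library 3. Pdk4, which restrains glucose oxidation, fell by 2.38 on the log2 scale (edgeR adjusted p = 0.0122), with 0.0658 and 0.0760 without GF library 1 or 2 and 0.0520 and 0.0764 without SPF library 2 or 3. The peptide hormone gene Pyy fell by 1.13 (edgeR adjusted p = 0.0346), with 0.111, 0.145 and 0.156 without GF library 1, 2 or 3 and 0.0531 and 0.0510 without SPF library 1 or 3. Over all alternatives the adjusted p ran from 0.000118 to 0.0699 for Slc5a8, from 0.000135 to 0.0764 for Pdk4 and from 0.000717 to 0.156 for Pyy (edgeR, DESeq2 or limma).

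In brain, groups of cell types showed 0 called members by edgeR, DESeq2 or limma voom, and 0 when adjusted over the list alone, with at most 3 members of a list at an unadjusted p below 0.05. Medians of the log2 fold change were 0.03 for 18 astrocyte markers, -0.01 for 21 myelin genes, 0.12 for 8 markers of macrophages and microglia, -0.13 for 26 glutamatergic genes and 0.01 for 22 GABAergic genes. Markers of blood-brain barrier junctions, 10 tested, had a median of 0.03, and 17 immediate early genes a median below 0.01. None of these lists was called by camera with all 6 libraries (limma adjusted p between 0.242 and 0.864). With 1 library left out some were, with adjusted p of 0.00214 and 0.0190 for myelin genes without GF library 1 or SPF library 1, 0.0440 and 0.00165 for glutamatergic genes without GF library 2 or SPF library 2, and 0.0361 for immediate early genes without GF library 1. The highest over 9 alternatives was 0.973, 0.970 and 0.982 for these 3 lists. Of other lists, striatal neuron markers were called as lower without GF library 3 (adjusted p = 3.32e-08) and clock genes as higher without GF library 1 (0.00176). Pituitary and hypothalamic hormones were called as lower without SPF library 1 (0.00111) and as higher without SPF library 2 (8.77e-05). Each of these 3 lists was at 0.919 by fry. Also called without 1 library were glucocorticoid receptor targets as higher without SPF library 3 (0.00255, up to 0.982 under other alternatives), ribosomal proteins as higher without GF library 2 (0.00685, up to 0.919) and cholesterol synthesis as lower without SPF library 1 (0.0317, up to 0.919).

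The clock genes Nr1d1 and Tef were higher in GF cecum, with log2 fold changes of 2.50 and 2.52, and differed from their change in brain by 2.28 and 2.48 (edgeR adjusted p = 0.0106 and 0.0131 for the interaction). Depth is argued against as the cause, since the mean of both genes stayed at 2.15 or higher in 10 draws of thinned cecum libraries, 1 of which had only 1 of the genes tested. Another hour of dissection in GF mice cannot be told apart, because the labels give no hour and the brain did not decide it. A clock phase score over 8 genes was higher in GF by 2.14 in cecum and by 0.31 in brain, where pairs of libraries differed by 0.06 to 0.61, neither absent nor near the cecum's size. The score includes Nr1d1 and Tef, taken up because they were called in cecum, so its size there is in part given by that choice. Of the other members, Dbp and Per3 were near the floor in SPF cecum, while Arntl and Npas2 were not and were lower in every GF library. Before TMM scaling, Dbp was at 2.59, 0 and 0 CPM and Per3 at 5.18, 0 and 2.29 CPM in SPF cecum libraries 1, 2 and 3.

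With 3 libraries against 3 there are only 10 splits of 6 libraries, too few for a share under 0.05. In cecum 1 of the 10, the real one, gave as many called genes (339, highest other 1), transcripts (302, highest other 0) and genes of changed usage (3, highest other 0). For cecum against brain it was also 1 of 10 (5062 genes, highest other 0). For called lists 6 of 10 splits gave as many in cecum (4, highest other 7) and 9 of 10 in brain (2, highest other 9). In brain all 10 gave as many genes, transcripts and genes of changed usage, since the real counts were 0, and the highest others were 78, 10 and 0. The split with 78 genes set GF libraries 1 and 2 and SPF library 1, the 3 with the highest cerebellar marker levels, against the rest, which points to a structure of these brain samples other than microbiota status.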
